A study of Mus musculus with 6 samples.

How the data were processed

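Liver RNA of 6 male KK/H1J mice, an inbred strain that becomes obese and diabetic through many genes, was measured on 6 one-colour arrays with biotin-labelled RNA, 1 mouse per array. Per the labels' protocols, 3 mice had received an adenovirus that carries a bisphosphatase-deficient form of the bifunctional enzyme PFK-2/FBPase-2 (BPD) and 3 a control adenovirus that carries green fluorescent protein (GFP), by tail vein. The stated dose was the same in both groups. Livers were taken 7 days later from freely fed animals of about 35 g. Groups and mouse numbers were taken from the sample titles (BPD mice 23, 28 and 36, GFP mice 22, 29 and 31). The numbers are not shared between the groups, so nothing pairs the mice.

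The deposited table holds 1 signal intensity per probe set and array. Per the submitters' processing notes these intensities were made with MAS5. The MAS5 version, its target value and any filter are not given in the sources used here. The deposited intensities are on a linear scale. Their mean after trimming 2% at each end was 499.9 on each of the 6 arrays, so each array had been scaled to a common trimmed mean near 500. No calls of presence or absence were used here. The table has 22690 probe sets, of which 64 are the manufacturer's controls and 22626 were analysed. All 6 columns of the table belong to the samples above, and 0 columns were left unused.

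Probe sets were named through the platform annotation supplied with the table. Of the 22626 probe sets, 20380 have 1 gene symbol, 691 have several and were named as no gene, and 1555 are unnamed here. The Entrez identifiers of 20351 matched the mouse gene table of assembly GRCm38.p6, which changed 0 symbols.

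Values were analysed as log2(signal + 16.3313), where the added constant is 10% of the median of all values (163.313). Differences on this scale understate changes of dim probe sets. The rule set before the data were examined asked for no further scaling if array medians and trimmed means lay within 25% of each other. The medians differed 1.46-fold between the highest and the lowest array, so by the same rule each array's log2 values were centred on its median. Probe sets were kept if their mean log2 value over all 6 arrays, blind to group, lay above the 40th percentile, which corresponds to a signal of 98.8. This left 13575 probe sets. A gene was represented by its kept probe set with the highest mean, which gave 8151 genes, 2881 of them with more than 1 kept probe set. Among genes with several kept probe sets, 1 (Tob2, named because the count was seen) had probe sets called in opposite directions.

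BPD and GFP livers were compared with limma version 3.58.1 in R version 4.3.3 (lmFit, then eBayes with an intensity trend, 2-sided). Each group had 3 arrays, with 4 residual degrees of freedom and 5.44 prior degrees of freedom. Adjusted p-values follow Benjamini and Hochberg over the 13575 probe sets, with a threshold of 0.05. Errors given with log2 differences are the standard errors (SE) of the moderated fit, and errors given with signals are SD over 3 mice. The number of arrays limits the precision.

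Gene lists, 34 in all with 691 entries, were written from textbook knowledge before the data were examined. They cover glucose, lipid, bile acid, drug and energy metabolism, sex-biased genes, the clock, stress and interferon responses, and markers of the cell types a liver piece can hold. Of the entries, 538 were measured, and 82 had no probe set named here and were not analysed here. The other 71 were too dim, except that Gapdh is named here only by control probe sets. The 32 lists with at least 3 measured members were tested with camera (preset correlation between genes of 0.01, 2-sided), with adjustment over these lists. The test was repeated with the correlation estimated from the residuals and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Beside the count of members called over all probe sets stands the count adjusted over the list alone. A further 10 lists were written after the genes with the largest changes had been seen, and appear only among the other observations.

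The rule for naming genes was also fixed beforehand. It takes the genes of the PFK-2/FBPase-2 family and the 10 largest rises and 10 largest falls among genes past the threshold with all BPD livers on 1 side of all GFP livers, leaving out names of clones. It then takes up to 4 members with the smallest p from each list described, and a fixed set of glucose and lipid genes. Members of that set without a probe set named here were not analysed here. Genes named outside the rule were chosen after their values were seen. In the results these are Lcn2, Saa3, Steap4, Phkg2, Cidec, Scd2, Acot1, Vnn1 and Hsp90aa1. Those among the other observations are marked there.

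RNA quality was checked with the ratios of 3' to 5' signal of the control probe sets for Gapdh and beta-actin. Groups were compared by an exact 2-sided permutation test over all 20 relabelings, whose smallest possible p is 0.1.

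The alternatives planned were other added constants (1% and 50% of the median), no filter or a filter at the 60th percentile, quantile normalization, eBayes without the trend or in its robust form, array weights, leaving out probe sets that can match several transcripts, and the Gapdh ratio as a covariate. Also planned were leaving out each mouse in turn, a threshold of 0.1, the mean of a gene's probe sets, and the set tests named above. Centring on the median had been planned as an alternative and became the main setting by the rule above. The deposited scaling and a covariate for the hybridisation controls (18 spike-in probe sets) were added after seeing the data. The fit was tested on simulated data for this comparison, with 200 of 13575 probe sets changed. It recovered 1.35% of changes of 0.5 on the log2 scale, 68.8% of changes of 1 and 100% of changes of 2. Of its 112 calls 5 were false, and it made 0 calls when nothing was changed. In the real comparison 3885 probe sets were called, which loosens the adjusted threshold. The shares recovered in the simulation therefore do not carry over to it, and smaller changes could pass there. In simulated lists with independent genes, 5 of 5 shifted lists were called and 0 of 25 unshifted lists. Labels give no hybridisation date or batch, so no batch could be taken from them.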

Results

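The study asked how the liver transcriptome of obese diabetic mice responds to an enzyme form that raises fructose 2,6-bisphosphate. PFK-2/FBPase-2 both makes and breaks down this sugar phosphate, a metabolite that stimulates glycolysis and restrains gluconeogenesis, and the BPD form lacks the activity that breaks it down. Livers of 3 BPD mice and 3 GFP control mice were compared 7 days after virus injection. The median signal of the arrays was 174, 197 and 177 for BPD mice 23, 28 and 36, and 135, 157 and 143 for GFP mice 22, 29 and 31. On each array between 11.8% and 16.0% of probe sets lay below the constant added before taking logarithms.

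The livers of the BPD mice differed widely from the GFP livers. Of the measured members, 25 of 27 genes of the cell cycle, 9 of 14 p53 targets, 14 of 20 macrophage markers, 4 of 8 neutrophil markers and 7 of 19 matrix genes rose. After centring, most measured genes of bile acid and cholesterol synthesis, of lipogenesis and among xenobiotic cytochromes fell, and so did most hepatocyte markers. With quantile normalization 13 of 19 bile acid and 12 of 19 cholesterol genes fell, but only 9 of 25 lipogenic genes, 10 of 23 cytochromes and 3 of 18 hepatocyte markers. None of the list calls held with an estimated correlation between genes, a form of the test with little power on 4 residual degrees of freedom. Of 8151 genes tested, 713 were higher and 1806 lower in BPD livers (limma, adjusted p under 0.05), and the change was at least 2-fold in 424 of the higher and 581 of the lower genes. Among probe sets, 1126 were higher and 2759 lower, so that 71.0% of the 3885 calls were lower. The balance of directions moved with the scaling between arrays. With the deposited scaling 2265 probe sets were higher and 1314 lower (36.7% lower), and with quantile normalization 1691 were higher and 1637 lower (49.2% lower). Called in the same direction under all 3 scalings were 1077 higher and 1097 lower probe sets, or 686 higher and 754 lower genes.

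The median gene differed between the groups by -0.22 on the log2 scale after centring, by 0.08 with the deposited scaling and by -0.06 with quantile normalization. Medians of gene lists are therefore given relative to the median of all genes. After centring, all BPD livers lay above all GFP livers in 1724 probe sets and below them in 4617, together 46.7%. Unrelated values would give 10%, but a difference of scale between the groups enters this share. Probe sets are also not independent of each other, so the excess over 10% is not a test. The number of calls depended on single mice, and fell to 2006 probe sets without BPD mouse 28. The calls for lower probe sets dropped to 1728 without GFP mouse 22 and to 1820 without GFP mouse 31, and those for higher probe sets to 729 without BPD mouse 23.

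**Figure D1:**
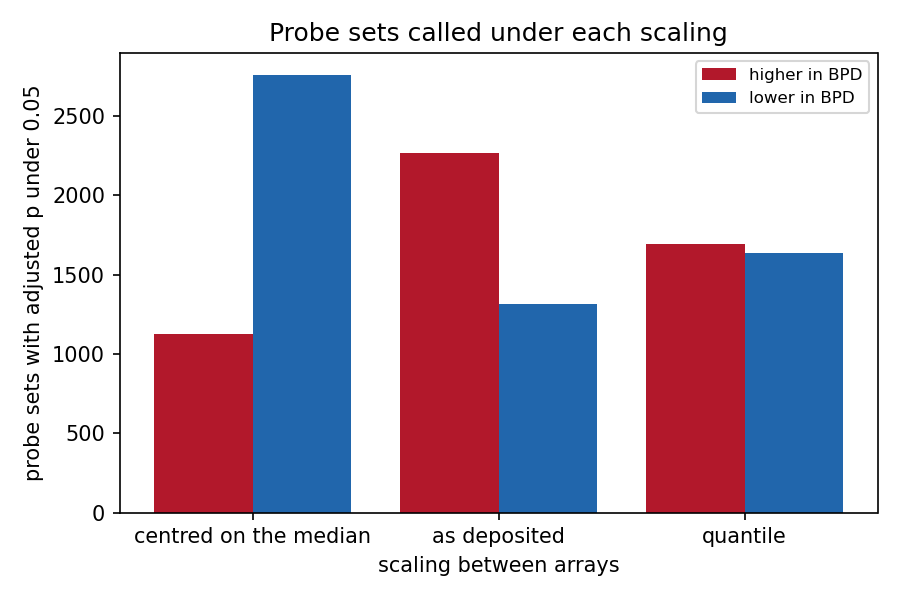
Number of probe sets with adjusted p under 0.05 (vertical axis, from 0) under 3 scalings between arrays (horizontal axis), with bars for probe sets higher and lower in BPD livers. Lower calls outnumber higher calls after centring on the median (2759 and 1126), and the order turns with the deposited scaling (1314 and 2265).

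The largest rise was that of Cyp4a14, a fatty acid hydroxylase induced through PPAR alpha. Its signal was 3432 ± 951 in BPD and 49.1 ± 24.5 in GFP livers (SD, n = 3 each), a log2 difference of 5.45 ± 0.30 or 43.7-fold (limma adjusted p = 6.7e-05). Ly6d, a surface protein of the Ly6 family, rose by 4.38 ± 0.35, and Mcm6, a subunit of the replicative helicase, by 4.18 ± 0.42. The calprotectin genes S100a8 (3.90 ± 0.51) and S100a9 (3.86 ± 0.60), abundant in neutrophils, rose too. The other genes among the 10 largest rises were Hemgn (3.66), Cd24a (3.61), Cox6b2 (3.58), Tnfrsf12a (3.57), which encodes the receptor of TWEAK, and Col1a1 (3.38), which encodes a chain of type I collagen. Tnfrsf12a, Col1a1 and Hemgn had mean signals of 23.1, 17.6 and 15.8 in GFP livers, close to the added constant, and in GFP liver 31 Mcm6 (13.5) and S100a9 (9.06) lay below it. The sizes of these 5 rises are uncertain. Cyp4a14, Cox6b2, Cd24a and S100a8 were also dim in GFP livers, with mean signals of 49.1, 65.4, 84.5 and 85.6. The added constant therefore understates their rises. Without BPD mouse 36 the rise was 4.70 for Tnfrsf12a, 4.30 for Col1a1, 4.60 for S100a8 and 4.46 for S100a9. It was 2.88 for Tnfrsf12a without BPD mouse 23 and 3.19 for S100a9 without GFP mouse 31.

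The largest fall was that of Hsd3b5, a steroid dehydrogenase of male mouse liver. It fell by 6.04 ± 0.94 on the log2 scale, from a signal of 3436 ± 696 to 145 ± 236 (SD, n = 3 each; limma adjusted p = 0.0022). The size of this fall is uncertain, since the signals of 2.41 and 15.4 in BPD livers 23 and 28 lie below the added constant and that of liver 36 was 418. The difference was -7.45 without BPD mouse 36 and -5.19 without BPD mouse 23. Cyp2c54 fell by 4.92 ± 0.22 and Cyp2c50 fell by 4.65 ± 0.26, both drug- and lipid-metabolising cytochromes. Ugt2b38 fell by 3.84 ± 0.30 and Prodh, the proline dehydrogenase, by 3.52 ± 0.26. Cyp8b1, the sterol 12-alpha-hydroxylase that sets the share of cholic acid, fell by 3.43 ± 0.45. The rest of the 10 were Upp2 (-3.39), the complement genes C8b (-3.31) and Masp1 (-3.16), and Thrsp (-3.04), a lipogenic gene. Without BPD mouse 36 the differences of Cyp8b1, Upp2 and Thrsp were -4.08, -4.07 and -3.68. The kept probe sets of Masp1 disagreed, with differences from -3.16 to 0.16. All 20 genes kept their direction and their call under every alternative run on them.

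**Figure D2:**
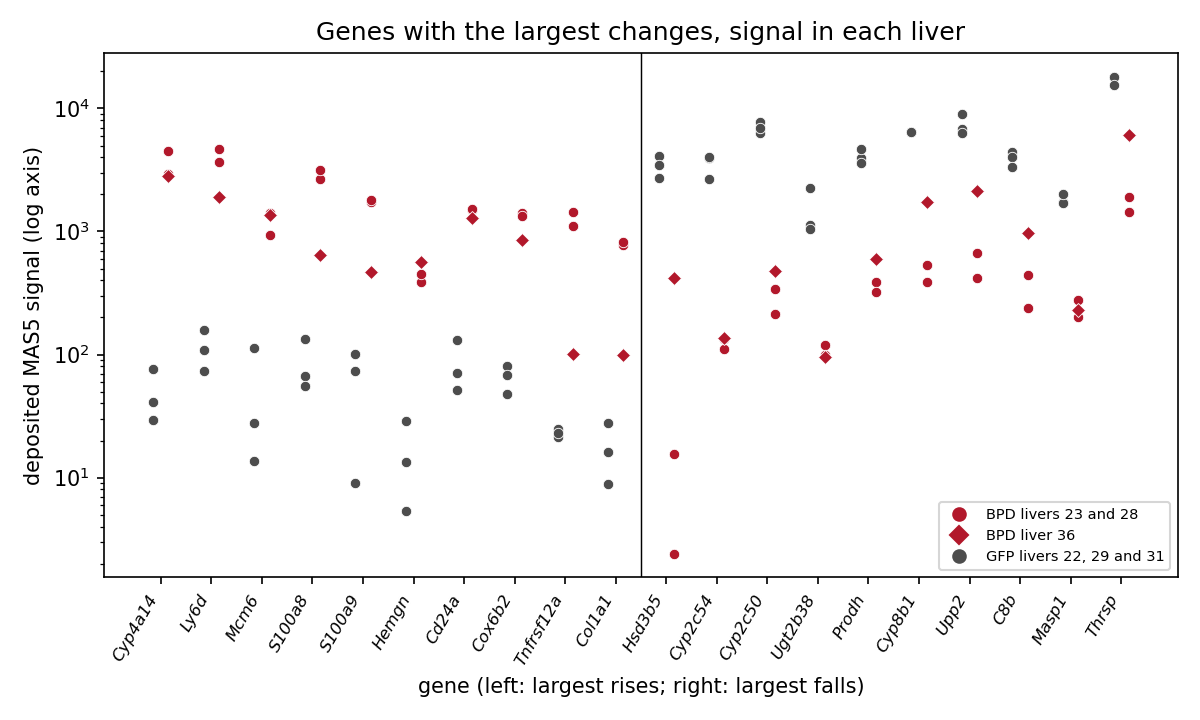
Deposited MAS5 signal (vertical log axis) of each liver for the 10 genes with the largest rise and the 10 with the largest fall (horizontal axis), with 1 point per mouse and no error bars. For each gene the BPD livers lie on 1 side of the GFP livers, with Cyp4a14 at 3432 on average in BPD and 49.1 in GFP livers, and liver 36 is drawn with its own symbol.

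Genes of the cell cycle and DNA replication rose together. Of 27 measured members 25 rose, 0 fell and 2 did not pass (also 25 adjusted over the list alone), and the list median lay 2.06 above that of all genes. Top2a, a topoisomerase of dividing cells, rose by 2.61 ± 0.23, cyclin E2 (Ccne2) by 2.84 ± 0.26, and the helicase subunits Mcm3 and Mcm5 by 2.10 ± 0.19 and 2.00 ± 0.18. Tested with camera, the list had an adjusted p of 5.8e-24, and the adjusted p = 0.154 with an estimated correlation. Targets of p53, the transcription factor of the DNA damage response, rose in 9 of 14 cases and 0 fell (9 adjusted over the list alone), with a list median 1.43 above that of all genes. Among them Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 2.32 ± 0.28, Phlda3 by 2.09 ± 0.16, Ccng1 by 1.58 ± 0.20 and Trp53inp1 by 1.37 ± 0.17. This list had a camera adjusted p of 2.0e-08, and the adjusted p = 0.154 with an estimated correlation. Whichever mouse was left out, at least 23 cell cycle genes and 8 p53 targets rose.

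For the lists, camera with its preset correlation called 18 of 32, 9 up and 9 down. With the correlation estimated from the residuals 0 were called, 3 had an unadjusted p under 0.05, and fry called 15. The estimated form rests on 4 residual degrees of freedom and has little power. Even the cell cycle list, with 25 of 27 members risen, had an unadjusted camera p of 0.0094 in that form. A list it did not call is therefore not shown to be unchanged. The calls for macrophage, matrix, interferon, antigen presentation, T and NK cell and gluconeogenesis genes were not made by fry, which also called 3 lists that camera did not. Other groupings of the same 6 arrays gave up to 18 list calls but 0 called genes. Those with 18 calls kept BPD mice 23 and 28 together and so still carry part of the difference between the groups. They do not show how many lists would be called without such a difference. The list calls stay limited, since they rest on a preset correlation of 0.01. Median and mean after centring differed in sign in the insulin signalling, fatty acid oxidation and erythroid lists. The camera direction was opposite to that of the centred median in the glycolysis, glycogen, heat shock and endothelial lists as well, none of which was called.

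**Figure D3:**
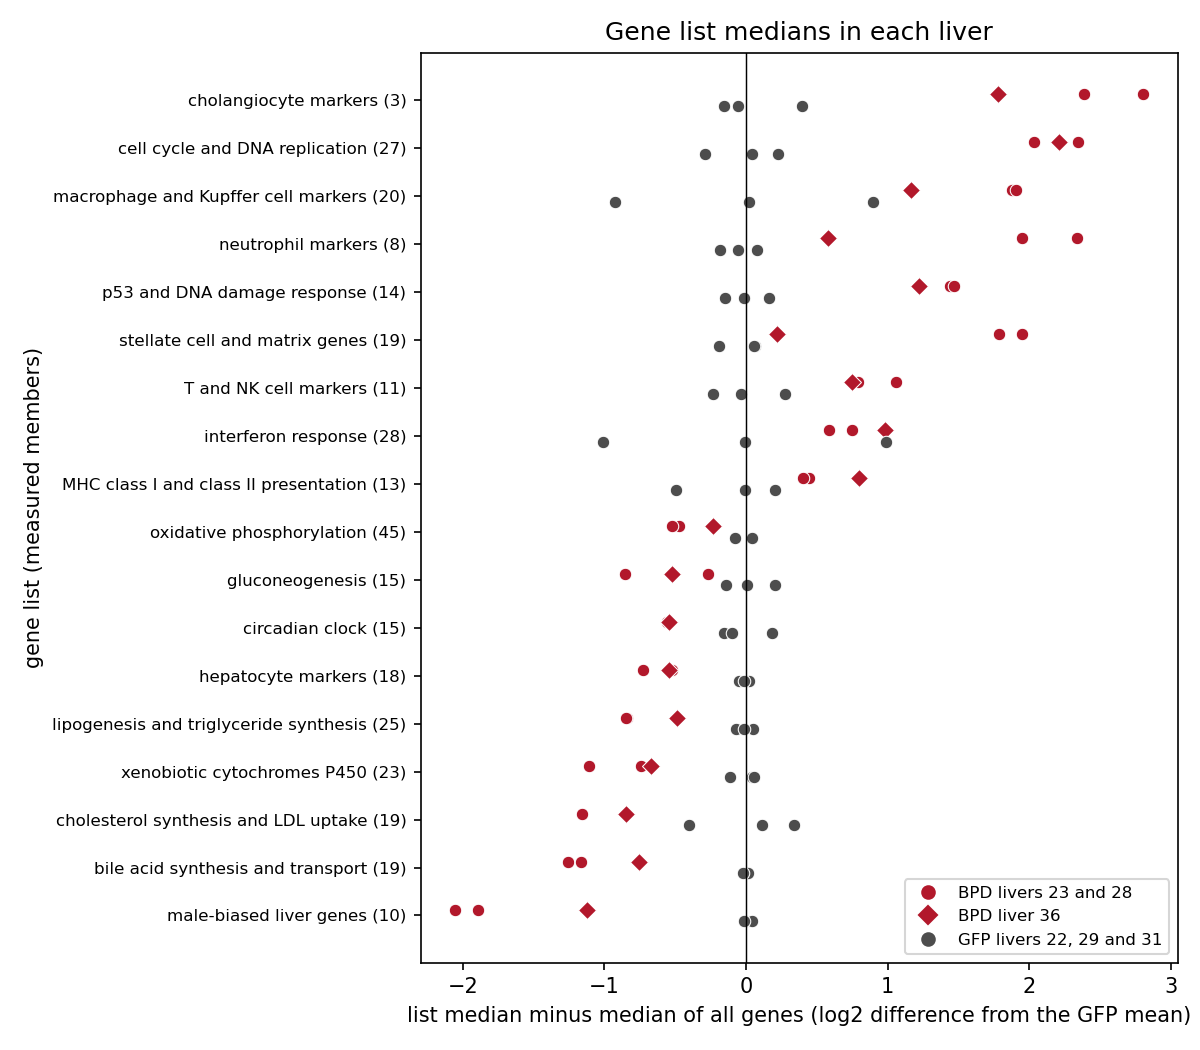
Median of each of the 18 called gene lists in each liver (horizontal axis), as log2 difference from the mean of the GFP livers minus the same median over all genes, with lists on the vertical axis, measured members in brackets and 1 point per mouse. BPD liver 36 is close to livers 23 and 28 for the cell cycle list and close to the GFP livers for the matrix list.

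Macrophage and Kupffer cell markers were higher in the BPD livers. Of 20 measured 14 rose and 0 fell (18 adjusted over the list alone), with a list median 1.73 above that of all genes. Lysozyme (Lyz2) rose by 2.42 ± 0.42, Cd68 by 1.68 ± 0.39, Aif1 by 1.62 ± 0.30 and the endotoxin co-receptor Cd14 by 1.51 ± 0.30. For macrophage markers the camera adjusted p was 1.8e-09, and the adjusted p = 0.409 with an estimated correlation. The number of risen markers dropped to 5 without BPD mouse 23 or BPD mouse 28, to 7 without GFP mouse 22 and to 8 without GFP mouse 31. It was 7 with the Gapdh ratio as a covariate, 8 with robust eBayes and 9 of 23 without the filter. Per mouse the median of this list relative to all genes was 0.90 in GFP liver 29 and 1.16 in BPD liver 36. Of 8 neutrophil markers 4 rose and 0 fell (6 adjusted over the list alone), namely S100a8 and S100a9, Ltf (1.89) and Ngp (2.02), with a list median 1.67 above that of all genes (camera adjusted p = 5.0e-05, and adjusted p = 0.409 with an estimated correlation). This count was 2 without BPD mouse 23, BPD mouse 28 or GFP mouse 22, and 3 of 11 without the filter.

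Of 11 T and NK cell markers 2 rose (5 adjusted over the list alone), namely Cd3g (0.93 ± 0.29) and Cxcr6 (0.77 ± 0.21), and none of the measured markers fell (camera adjusted p = 0.0018, and adjusted p = 0.409 with an estimated correlation). The count was 5 without GFP mouse 29 and 1 without BPD mouse 23, and 0 passed without BPD mouse 28, GFP mouse 22 or GFP mouse 31. It was 2 of 24 without the filter, 4 with the larger added constant and 5 with the deposited scaling. Of 5 B and plasma cell markers 0 passed (0 adjusted over the list alone), 1 had an unadjusted p under 0.05, and the list was not called (camera adjusted p = 0.177). Without BPD mouse 36, 2 of them rose and the list was called (camera adjusted p = 0.0416). Of 28 interferon response genes 4 rose and 0 fell (0 adjusted over the list alone), namely Cxcl10 (1.60 ± 0.44), Oas2 (1.32 ± 0.39), Gbp2 (1.89 ± 0.57) and Rsad2 (1.68 ± 0.55), with a list median 0.65 above that of all genes (camera adjusted p = 2.5e-05, and adjusted p = 0.573 with an estimated correlation). The GFP livers varied widely in this list, with medians relative to all genes of 0.99, -0.0035 and -1.01 for mice 22, 29 and 31. Leaving out GFP mouse 22 raised the count to 14, whereas it was 0 without BPD mouse 28 or GFP mouse 29, 1 without BPD mouse 23 or GFP mouse 31, and 2 without BPD mouse 36. It was 1 with robust eBayes, with the Gapdh covariate and without the filter, and 8 with the deposited scaling.

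Of 13 genes of antigen presentation 2 rose and 2 fell (5 and 2 adjusted over the list alone). The class II genes H2-Ab1 and H2-Eb1 rose by 1.14 ± 0.27 and 1.18 ± 0.31. Neither passed without BPD mouse 28 (adjusted p of 0.056 and 0.077), nor did H2-Eb1 without BPD mouse 23, GFP mouse 22 or GFP mouse 31 (adjusted p of 0.062, 0.060 and 0.053). The class I genes B2m and H2-K1 fell by 0.52 ± 0.11 and 0.43 ± 0.13, but did not pass with the deposited scaling (-0.22 and -0.13) and turned to 0.13 and 0.24, without passing, with quantile normalization. The fall of H2-K1 passed with a mouse left out only when that was GFP mouse 31, and its 4 kept probe sets ranged from -0.75 to 0.07. The list had a camera adjusted p of 0.0244, and the adjusted p = 0.573 with an estimated correlation. It was not called without GFP mouse 31 (camera adjusted p = 0.139), with the deposited scaling (0.0603) or with the Gapdh ratio as a covariate (0.105). Of its members 6 rose and 0 fell with the deposited scaling, and 4 and 0 with quantile normalization. The number of risen members was 0 without BPD mouse 28, 1 without BPD mouse 23 or GFP mouse 31, 4 without BPD mouse 36 and 5 without GFP mouse 29. Acute phase genes went both ways, with 4 of 24 risen and 14 fallen (4 and 17 adjusted over the list alone). Serum amyloid P (Apcs) fell by 1.43 ± 0.16, Orm1 by 1.10 ± 0.19, and the fibrinogen genes Fgb and Fgg by 0.79 ± 0.14 and 0.76 ± 0.13, although neither fibrinogen gene passed with quantile normalization. Socs3, a feedback inhibitor of cytokine signalling, rose by 1.35 ± 0.24, though not without probe sets that can match several transcripts (0.54). The other risers were Lcn2 (2.25), Saa3 (1.51) and Steap4 (0.71). This list was not called (camera adjusted p = 0.0572), but was without BPD mouse 28, BPD mouse 36 or GFP mouse 31 (camera adjusted p of 0.0399, 0.0296 and 0.0269) and with the deposited scaling (0.0029). It was also called by fry (down, adjusted p = 0.0399), with the larger added constant (0.0457), with array weights (0.0487), without probe sets that can match several transcripts (0.0398) and with the Gapdh covariate (0.0315). Of its genes 9 fell with the deposited scaling and 3 with quantile normalization.

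Matrix and stellate cell genes rose in part. Of 19 measured 7 rose and 0 fell (11 adjusted over the list alone), and the count was 16 without BPD mouse 36. Without the filter 5 of 20 rose. Galectin-1 (Lgals1) rose by 2.07 ± 0.20, vimentin (Vim) by 2.04 ± 0.33 and Col4a1, a chain of basement membrane collagen, by 1.44 ± 0.20. The list median lay 1.33 above that of all genes (camera adjusted p = 1.5e-07, and adjusted p = 0.446 with an estimated correlation). Per mouse the median of the list relative to all genes was 1.95 and 1.78 in BPD livers 23 and 28 but 0.22 in liver 36. All 3 cholangiocyte markers bright enough to pass the filter rose, and without the filter 3 of 10 rose (3 of the 3 adjusted over the list alone), with Cd24a at 3.61 ± 0.28, Krt23 at 2.11 ± 0.36 and Anxa5 at 0.60 ± 0.19 (camera adjusted p = 3.7e-04, and adjusted p = 0.409 with an estimated correlation). Cd24a and Krt23 had mean signals of 84.5 and 50.6 in GFP livers, under the 98.8 of the filter. Their higher signal in BPD livers thus let them pass it, so 3 of 3 risen is partly set by the filter. The call of Anxa5 was lost on leaving out any mouse other than BPD mouse 36, with adjusted p from 0.077 to 0.13.

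Endothelial markers did not move as a group. Of 13 measured 1 rose, the hyaluronan receptor Lyve1 (1.69 ± 0.36), and 1 fell, the VEGF receptor Kdr (-0.62 ± 0.20), with 1 and 0 adjusted over the list alone (camera adjusted p = 0.492). The other kept probe set of Lyve1 was at 0.66. The fall of Kdr did not pass with the deposited scaling or quantile normalization, nor with a mouse left out other than GFP mouse 31 (adjusted p from 0.077 to 0.14). Among 5 erythroid markers the anion exchanger of red cells, Slc4a1, rose by 2.99 ± 0.36 and the transferrin receptor Tfrc by 1.32 ± 0.27, while Alas2, the first enzyme of haem synthesis in red cell precursors, fell by 1.62 ± 0.20 (2 risen and 1 fallen also adjusted over the list alone, camera adjusted p = 0.288). The 2 measured markers of pancreas, Cela1 (-0.20 ± 0.21) and Prss2 (-0.17 ± 0.26), did not pass (0 had an unadjusted p under 0.05), and with 2 members the list was not tested.

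Hepatocyte markers fell. Of 18 measured 17 fell and 0 rose (18 adjusted over the list alone), with a list median 0.63 below that of all genes. Hpd, an enzyme of tyrosine breakdown, fell by 1.53 ± 0.14, the urea cycle enzymes Otc and Cps1 by 1.43 ± 0.19 and 0.96 ± 0.12, and antithrombin (Serpinc1) by 0.83 ± 0.12. The list's camera adjusted p was 5.6e-07, and the adjusted p = 0.409 with an estimated correlation. The number of fallen markers was 13 with the deposited scaling and 3 with quantile normalization, where Serpinc1 did not pass.

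Alongside the hepatocyte markers, genes of bile acid synthesis and transport fell, 15 of 19 with 0 risen (15 adjusted over the list alone). The list median lay 1.10 below that of all genes. The bile acid CoA ligase Slc27a5 fell by 2.53 ± 0.24, the uptake transporters Slc10a1 and Slco1a1 by 2.44 ± 0.30 and 2.36 ± 0.28, and Cyp27a1 by 1.39 ± 0.14. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.99 ± 0.36 (adjusted p = 0.0043). With camera the adjusted p was 5.5e-06 for the list, and the adjusted p = 0.409 with an estimated correlation. Xenobiotic cytochromes and their regulators fell in 15 of 23 cases with 0 risen (16 adjusted over the list alone), with a median 0.80 below that of all genes. Next to Cyp2c54 and Cyp2c50, Nr1i3, the nuclear receptor CAR, fell by 2.52 ± 0.17 and Cyp1a2 by 1.84 ± 0.15 (camera adjusted p = 3.1e-05, and adjusted p = 0.409 with an estimated correlation). With quantile normalization 10 of the 23 fell.

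Genes that are higher in male than in female mouse liver fell in all 10 measured cases (10 adjusted over the list alone), with a list median 1.66 below that of all genes. Beside Hsd3b5, Ugt2b1 fell by 2.40 ± 0.32, Cyp7b1 by 2.10 ± 0.30 and Egfr by 1.35 ± 0.17 (camera adjusted p = 1.6e-05, and adjusted p = 0.409 with an estimated correlation). The 5 kept probe sets of Egfr ranged from -1.45 to -0.45. The 3 measured genes of the female-biased list did not pass (0 adjusted over the list alone, 0 with an unadjusted p under 0.05), at 0.86 ± 0.40 for Acot3, 0.81 ± 0.39 for Cyp2b9 and -0.32 ± 0.38 for Fmo2 (camera adjusted p = 0.213). Without the filter on dim probe sets 3 of 12 measured members rose and the list was called up (camera adjusted p = 0.0248).

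In the PFK-2/FBPase-2 family itself only Pfkfb3 was measured, at -0.08 ± 0.25 (adjusted p = 0.837), and its sign turned with the deposited scaling (0.22) and without BPD mouse 36 (0.16). Genes of glycolysis and glucose uptake went both ways, with 3 of 16 risen and 4 fallen (4 and 5 adjusted over the list alone). The liver pyruvate kinase gene Pklr fell by 2.24 ± 0.25 (adjusted p = 6.5e-04) and Aldoc by 1.52 ± 0.21. Pkm and Hk1, a pyruvate kinase and a hexokinase, rose by 1.73 ± 0.28 and 0.97 ± 0.15. As deposited 6 members rose and 3 fell, and with quantile normalization 4 rose and 2 fell. The list was not called (camera adjusted p = 0.515). Its median and mean after centring were -0.15 and -0.09, while its median relative to all genes was 0.07.

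Genes of gluconeogenesis mostly fell, 10 of 15 with 1 risen (11 and 1 adjusted over the list alone), and the list median lay 0.52 below that of all genes. The glucose 6-phosphate transporter Slc37a4 fell by 1.79 ± 0.22, Got1 by 1.44 ± 0.23 and pyruvate carboxylase (Pcx) by 1.11 ± 0.21. The gene that rose was Pck2, the mitochondrial PEP carboxykinase (2.30 ± 0.27). Pck1, the cytosolic form, fell by 0.80 ± 0.23 (adjusted p = 0.0301), a call lost with the deposited scaling (-0.50) and with quantile normalization (-0.23), as well as without BPD mouse 28, GFP mouse 22 or GFP mouse 31 (adjusted p of 0.10, 0.10 and 0.095). G6pc, the catalytic subunit of glucose 6-phosphatase, was at -0.63 ± 0.23 and did not pass (adjusted p = 0.0625), except without BPD mouse 23 (adjusted p = 0.036). Gluconeogenesis had a camera adjusted p of 0.0174, the adjusted p = 0.573 with an estimated correlation, and the call was lost with quantile normalization (adjusted p = 0.0698, 3 fallen). With the deposited scaling, and without BPD mouse 28, GFP mouse 22 or GFP mouse 31, 6 members fell.

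Targets of ChREBP, the glucose-responsive transcription factor, fell in 9 of 14 cases with 1 risen (10 and 2 adjusted over the list alone). Besides Pklr, Fasn fell by 2.02 ± 0.23 (adjusted p = 7.4e-04) and Acly by 1.25 ± 0.18, while the hormone gene Fgf21 rose by 1.04 ± 0.19. The gene of ChREBP itself, Mlxipl, fell by 0.81 ± 0.20, a call lost with the deposited scaling (-0.50) and quantile normalization (-0.42), and without BPD mouse 23, BPD mouse 28 or GFP mouse 22 (adjusted p of 0.054, 0.066 and 0.056). The list was not called (camera adjusted p = 0.0572), but was without BPD mouse 36 or GFP mouse 31 (camera adjusted p of 0.0296 and 0.0416) and with the deposited scaling (0.0083). It was also called by fry (down, adjusted p = 0.0289), with the larger added constant (0.0399), without a filter (0.0248), with the 60th percentile filter (0.0185) and with the Gapdh covariate (0.0384). With the deposited scaling 4 of the targets fell, as they did without BPD mouse 28, and 5 without GFP mouse 22. With quantile normalization 5 fell and 2 rose.

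The insulin signalling list had 1 risen and 2 fallen members of 14 (1 and 0 adjusted over the list alone), the risen one being Socs3 and the fallen ones Foxo1 (-0.74) and Pik3ca (-0.50) (camera adjusted p = 0.270). As deposited 5 members rose and 0 fell, with quantile normalization 3 rose and 1 fell, and 0 fell without BPD mouse 28, GFP mouse 22 or GFP mouse 31. Foxo1 did not pass with either other scaling, nor Pik3ca with the deposited one. The other kept probe set of Pik3ca was at -0.01. Of 14 glycogen genes 1 rose, the brain-type phosphorylase Pygb (2.70 ± 0.57), and 4 fell (2 and 4 adjusted over the list alone), namely Ugp2, which makes UDP-glucose (-1.05 ± 0.18), Pygl (-0.96), Gys2 (-0.89) and Phkg2 (-0.53) (camera adjusted p of the list 0.898). Of the glycogen genes 4 rose and 2 fell with the deposited scaling, and with quantile normalization 2 rose and 1 fell, with Gys2 and Phkg2 past the threshold under neither and Pygl not under the latter. Only 1 glycogen gene fell without BPD mouse 28 or GFP mouse 22, and 2 without GFP mouse 31. In the pentose phosphate pathway Rpia rose (0.84 ± 0.17) and H6pd (-0.98 ± 0.20) and Tkt (-0.55 ± 0.15) fell among 7 genes (1 and 2 adjusted over the list alone, camera adjusted p = 0.898). Under either other scaling 2 of the 7 rose and 1 fell. The call of Tkt was lost with the deposited scaling (-0.25), with quantile normalization (-0.02) and on leaving out BPD mouse 28, BPD mouse 36, GFP mouse 22 or GFP mouse 31 (adjusted p from 0.052 to 0.098).

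Lipogenic genes fell. Of 25 measured 15 fell and 2 rose (15 and 3 adjusted over the list alone), with a list median 0.68 below that of all genes. Acss2, which makes acetyl-CoA from acetate, fell by 2.80 ± 0.26, and Fasn, the fatty acid synthase, and Thrsp fell as given above. Elovl5 fell by 1.07 ± 0.15, and Scd1, the stearoyl-CoA desaturase, by 1.42 ± 0.25, with its other probe set at -2.95. Srebf1, which encodes a master regulator of lipogenesis, fell by 0.93 ± 0.21, and neither it nor Scd1 passed with quantile normalization. The 2 that rose were Cidec (1.33 ± 0.28), of lipid droplets, and Scd2 (1.22 ± 0.31). In the camera test the adjusted p was 0.0043, and the adjusted p = 0.553 with an estimated correlation. With quantile normalization 9 members fell.

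Genes of cholesterol synthesis and LDL uptake fell in all 19 measured cases (19 adjusted over the list alone), and the list median lay 0.99 below that of all genes. Fdps, which makes farnesyl diphosphate, fell by 2.69 ± 0.19, the sterol oxidase Msmo1 by 2.46 ± 0.26, Tm7sf2 by 2.23 ± 0.23 and lanosterol synthase (Lss) by 1.41 ± 0.17. By camera the list's adjusted p was 5.6e-07, and the adjusted p = 0.446 with an estimated correlation. The count of fallen genes was 11 with the deposited scaling and 12 with quantile normalization, 11 without BPD mouse 28 or GFP mouse 31, and 12 without GFP mouse 29.

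Genes of fatty acid oxidation and ketogenesis went both ways, with 5 of 24 risen and 8 fallen (6 and 9 adjusted over the list alone). Next to Cyp4a14, the thioesterases Acot2 and Acot1 rose by 2.57 ± 0.23 and 1.19 ± 0.34, Vnn1 by 2.62 ± 0.47 and Fgf21 as given above. The transporter Slc27a2 fell by 1.07 ± 0.17 and the peroxisomal thiolase Acaa1b by 0.85 ± 0.14, the latter without passing under quantile normalization. Cpt1a, the gate of mitochondrial fatty acid oxidation, was at -0.24 ± 0.17 (adjusted p = 0.306), and its sign turned with the deposited scaling (0.06) and quantile normalization (0.25). The list was not called (camera adjusted p = 0.397). As deposited 9 of its genes rose and 5 fell. With quantile normalization 11 rose and 2 fell, and it was called up (adjusted p = 8.8e-04). After centring its median was -0.14 and its mean 0.28.

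Genes of oxidative phosphorylation fell in 35 of 45 cases with 0 risen (40 adjusted over the list alone), with a list median 0.41 below that of all genes. Sdhb, of complex II, fell by 1.06 ± 0.17, Ndufs8, of complex I, by 1.39 ± 0.24, Uqcrq by 0.76 ± 0.14 and Cox6c by 0.71 ± 0.14. Its camera adjusted p was 5.6e-07, and the adjusted p = 0.573 with an estimated correlation. This fall depended on the scaling, with 15 fallen members with the deposited scaling, and 3 fallen and 1 risen with quantile normalization, where the list was not called (adjusted p = 0.303) and neither Uqcrq nor Cox6c passed. It also depended on single mice, with 15 fallen without BPD mouse 28, 18 without GFP mouse 22 and 20 without GFP mouse 31.

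In the citric acid cycle list 11 of 23 genes fell and 0 rose (12 and 1 adjusted over the list alone), with the pyruvate dehydrogenase kinases Pdk1 and Pdk2 at -2.26 ± 0.29 and -1.29 ± 0.23. The list was not called (camera adjusted p = 0.177), but was without BPD mouse 36 (camera adjusted p = 0.0397). With the deposited scaling 6 members fell and 6 rose, with quantile normalization 3 fell and 5 rose, and 6 fell without BPD mouse 23, BPD mouse 28, GFP mouse 22 or GFP mouse 31. Clock genes fell in 9 of 15 cases with 0 risen (9 adjusted over the list alone), among them Nfil3 (-1.63 ± 0.27) and Per3 (-0.79 ± 0.16), with a list median 0.60 below that of all genes (camera adjusted p = 0.0079, and adjusted p = 0.409 with an estimated correlation). With either other scaling 5 clock genes fell, and the list was not called with the 60th percentile filter (camera adjusted p = 0.0760).

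Of 23 genes of the unfolded protein response and ATF4 targets 1 rose, the stress-induced factor Atf3 (1.53 ± 0.29), and 7 fell (2 and 7 adjusted over the list alone), among them Herpud1 (-1.77 ± 0.27), Hyou1 (-1.14 ± 0.20) and the chaperone cofactor Dnajc3 (-0.88 ± 0.15). The list was not called by camera (adjusted p = 0.898) but was by fry (down, adjusted p = 0.0409), and 4 members fell without BPD mouse 28. As deposited 4 rose and 3 fell, and with quantile normalization 3 rose and 3 fell. Of 18 genes of the heat shock and oxidative stress response 2 rose and 5 fell (3 and 5 adjusted over the list alone). The glutathione transferase Gsta2 fell by 2.00 ± 0.29 and Gclm, of glutathione synthesis, by 1.15 ± 0.17, while sulfiredoxin (Srxn1) rose by 1.08 ± 0.19 and Hsp90aa1 by 0.62 ± 0.14 (camera adjusted p of the list 0.898). Without BPD mouse 28 or GFP mouse 31, 3 of them fell. The counts were 3 risen and 2 fallen with the deposited scaling and 4 and 3 with quantile normalization.

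The arrays of a group resembled each other more than those of the other group. Pearson correlations across probe sets, which are not independent replicates, were 0.950 to 0.976 within groups and 0.851 to 0.942 between groups. The first principal component held 69.8% of the variance and separated the groups, with BPD liver 36 at 23.0 against 47.3 and 50.7 for BPD livers 23 and 28 and values from -53.7 to -28.4 for GFP livers. The hybridisation controls were brightest on the arrays of BPD mouse 23 and GFP mouse 22, with a mean log2 signal of 11.49 and 11.45 against at most 11.01 on the others. With these controls as a covariate 3748 probe sets were called, 1012 higher and 2736 lower. Without liver 36, 1228 probe sets were higher and 2763 lower. The ratio of 3' to 5' signal was 0.781 ± 0.071 in BPD and 0.827 ± 0.063 in GFP livers for Gapdh (SD, n = 3 each; exact permutation p = 0.5) and 1.42 ± 0.29 and 1.52 ± 0.10 for beta-actin (exact permutation p = 0.7), in a design whose smallest possible p is 0.1.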

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

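The tests of tissue makeup, of scaling and of liver 36 in this part were chosen only after the results they concern were seen, and the regroupings of the arrays were planned before. Groups of 3 were not tested for single outlying mice.

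Control probe sets outside the comparison were higher in every BPD liver than in any GFP liver in 3 cases. The 3' and middle probe sets for beta-actin had mean signals of 14000.3 and 11519.1 in BPD livers against 11161 and 8141 in GFP livers. The middle probe set for the transferrin receptor had 48.3 against 3.52, with BPD liver 23 at 5.56, near the GFP livers. Another 5 were lower in every BPD liver than in any GFP liver. They were the 3', 5' and middle probe sets for Gapdh (9945, 12756 and 11218 against 12601, 15293 and 13841), that for murine B2 (18578 against 21495) and the 3' probe set for pyruvate carboxylase (2286 against 4222). These are deposited signals without centring, a difference of scale between arrays enters them, and their cause was not tested.

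Hepatocyte genes fell while macrophage, matrix and cell cycle genes rose, a pattern that a lower share of hepatocyte RNA could produce in part. A loss of hepatocytes with the other cells unchanged, as the whole cause, would raise markers of the other cell types alike. The macrophage list's median lay 1.56 above that of the endothelial list over the BPD mice (SD 0.19, n = 3), against 0.02 (SD 0.59) in GFP mice. These values argue against such a loss alone. They cannot exclude a changed cell makeup, because a gain of macrophages would lower the hepatocyte share and give the same difference. The bile acid list lay below the hepatocyte markers in each BPD liver, at -0.73, -0.44 and -0.21 from them in mice 23, 28 and 36. In GFP livers 22, 29 and 31 it lay at 0.06, -0.01 and -0.01. The bile acid list thus fell further than the marker list in these 3 mice. The size of this difference varied widely (mean -0.46, SD 0.26, n = 3). Whether a general loss of hepatocyte RNA accounts for the fall of bile acid genes therefore cannot be told apart from a fall of their own. A gain of macrophages, a change in the macrophages themselves and the biological effect of the BPD enzyme stay open, and the last has no separate test here. Each group received its own virus, and no liver without virus was measured. A difference between the virus preparations therefore cannot be told apart from an effect of the enzyme.

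More probe sets were called lower than higher after centring, whereas 36.7% of calls were lower with the deposited scaling and 49.2% with quantile normalization. The deposited scaling adds the same 0.301 to every log2 difference, so its balance follows by construction and does not test the cause. The array medians were higher in BPD livers (182 ± 13 against 145 ± 11, SD, n = 3 each; exact permutation p = 0.1, the smallest the design allows), while the trimmed means were equal by construction. No scaling here is known to be the right one, so an effect of scaling and a true imbalance between the groups cannot be told apart.

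BPD liver 36 lay closer to the GFP livers than livers 23 and 28 did. Over the 2566 genes called without it, its differences had a slope of 0.675 on the mean of the other BPD livers, against 1.02 and 1.12 for livers 23 and 28 treated likewise. In this liver the slope was 0.92 in the cell cycle list and 0.24 in the matrix list, a difference of 0.675. That difference ranged from 0.66 to 0.69 with 1 of the other 5 mice left out (jackknife SE 0.03). Liver 36 stays in every such fit, so the SE measures neither its own variation nor the scatter over genes. Whether its response was weaker by 1 factor in all lists is therefore not decided. RNA degradation is argued against by its beta-actin ratio of 1.26, within the range of the other arrays (1.23 to 1.75). A smaller amount of virus reaching this liver, or another stage of the response, may also give such a pattern and was not tested.

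The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3885 probe sets and 2519 genes, each the only 1 of the 10 splits with as many, and the highest other split gave 0 of either. For gene lists the real split gave 18 calls, and so did the highest of the others, with 3 of the 10 splits at 18. Both of the other splits at 18 put BPD mice 23 and 28 with 1 GFP mouse, so they keep part of the difference between the groups. In mixed splits that difference also enters the spread within groups, which lowers the calls of probe sets and genes. The counts of the other splits therefore do not measure what no difference would give.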

How the results depend on the processing

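The deposited scaling and the covariate for the hybridisation controls were chosen only after the results were seen, and the other alternatives were planned. No paired analysis was possible because the mouse numbers are not shared between the groups. Centring on the median, planned as an alternative, became the main setting and has no value of its own. Signal over background was not given per probe set, and dim probe sets carry little information.

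Counts of called probe sets and genes stayed within 1.5 times the main counts except as follows, and the cause was not tested. With the filter at the 60th percentile, which tests 9050 probe sets, 698 probe sets and 443 genes were higher. With quantile normalization 1691 probe sets were higher, 1637 lower and 1057 genes lower. With the deposited scaling 2265 probe sets were higher and 1314 lower, and 1406 genes were higher and 902 lower. Leaving out each mouse in turn gave 2006 to 3991 probe sets (628 to 1228 higher, 1378 to 2763 lower), 1328 to 2566 genes (403 to 800 higher, 925 to 1766 lower) and 18 to 22 lists. For probe sets and genes the low ends came without BPD mouse 28, which leaves fewer samples. Without BPD mouse 23, 729 probe sets and 453 genes were higher. Lower probe sets and genes numbered 1728 and 1129 without GFP mouse 22, and 1820 and 1193 without GFP mouse 31. The number of lists called was 0 with an estimated correlation, a form with little power here, against 18. The differences in the Gapdh and beta-actin ratios kept their sign on the log2 scale.

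Directions turned for the lists and genes given next, and the cause was not tested. For lists the value is the median relative to all genes and the direction that of the set test, so they can differ. Glycogen metabolism turned without a filter (0.0379), with the 60th percentile filter (-0.0756), with fry (0.0314) and with the deposited scaling (0.0314), and ranged from -0.0560 to 0.0282 with a mouse left out. Heat shock and oxidative stress turned without shared probe sets (-0.0592), with fry (-0.0629) and with the deposited scaling (-0.0629), and ranged from -0.114 to 0.0370. The unfolded protein response turned with quantile normalization (0.204), without shared probe sets (0.0582) and with the Gapdh covariate (0.0818), and ranged from -0.00376 to 0.116. Endothelial markers turned with the 60th percentile filter (-0.0698) and fry (0.0438), and ranged from -0.127 to 0.337. The pentose phosphate pathway turned with quantile normalization (0.0435) and glycolysis with fry (0.0726). None of these lists was called in the main setting. Among genes, B2m (0.13) and H2-K1 (0.24), both called lower in the main setting, turned with quantile normalization, as did Cpt1a (0.25) and Cela1 (0.0010). With the deposited scaling Cpt1a (0.0563), Pfkfb3 (0.22), Cela1 (0.10), Prss2 (0.14) and Klf1 (0.15) turned. Pfkfb3 also turned with array weights (0.0064) and ranged from -0.23 to 0.16 with a mouse left out, Prss2 with the mean of probe sets (0.0085) and from -0.37 to 0.0757, and Fmo2 without shared probe sets (0.29).

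Of 144 genes, 121 kept direction and call with quantile normalization and 125 with the deposited scaling, 19 and 10 lost the call. Of 32 lists, 27 kept both with either scaling.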

Other observations

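The gene lists in this part and the test of fatty acid oxidation genes were chosen only after the genes with the largest changes had been seen, so their counts are not independent evidence of a direction.

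Secreted and catabolic functions of the liver beyond the lists above fell widely. Of 26 measured complement and coagulation factors 24 fell and 0 rose, with a list median 0.78 below that of all genes. Examples are Klkb1, which encodes plasma prekallikrein (-1.82), C8a (-1.71) and coagulation factor XI (F11, -1.52). Of 27 genes of amino acid catabolism 24 fell and 0 rose, with a median 1.20 below that of all genes, including ornithine aminotransferase (Oat, -2.76), Haao of tryptophan breakdown (-2.18) and the glycine methyltransferase Gnmt (-1.53). Of 19 conjugating transferases 16 fell and 0 rose, with Nat8 at -2.76 and Ugt3a2 at -2.35. In the growth hormone axis 6 of 8 fell and 0 rose, among them Igfals (-2.43), Socs2 (-1.31), Ghr (-1.26) and Igf1 (-0.90). Of 19 peroxisomal genes 10 fell and 0 rose, but 7 fell and 1 rose with the deposited scaling and 4 fell and 2 rose with quantile normalization, where 16 complement and coagulation genes fell and 2 rose. Also, of 29 proteasome subunits 6 fell and 0 rose, a count that was 0 with the deposited scaling. None of 22 ribosomal protein genes was called by limma after centring (2 had an unadjusted p under 0.05), whereas 6 rose with the deposited scaling and 13 with quantile normalization. With camera the adjusted p-values were 2.4e-09 for complement and coagulation, 1.2e-11 for amino acid catabolism, 2.4e-08 for transferases, 0.0035 for the growth hormone axis, 0.0021 for peroxisomes, 0.0725 for the proteasome and 0.431 for ribosomal proteins. With an estimated correlation the first 5 had adjusted p = 0.238, 0.205, 0.205, 0.205 and 0.436.

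Other genes rose with the macrophage and cell cycle markers. Of 20 cytoskeletal and annexin genes 15 rose and 0 fell, with a median 1.46 above that of all genes, led by Rhoc (2.67), Tubb6 (2.27), Tmsb10 (2.27) and Anxa2 (2.09). Of 13 genes of lysosomes and lipid-laden macrophages 7 rose, among them Gpnmb (3.08), Mmp12 (2.94) and galectin-3 (Lgals3, 2.60), and 1 fell, the cathepsin gene Ctsl (-0.78), a fall that did not pass with quantile normalization. Of 8 measured genes of fetal liver and progenitor cells 4 rose and 0 fell, namely Ly6d, Cd24a, Tnfrsf12a and Sox4 (2.57), of which the first 3 had entered the list because they were among the largest rises. The camera adjusted p-values were 1.2e-11, 7.1e-05 and 3.5e-05, with adjusted p = 0.205, 0.244 and 0.205 with an estimated correlation. The genes of this part were chosen after their values were seen.

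A hypothesis was that the rise of Cyp4a14, a target of PPAR alpha, was part of a rise shared by the fatty acid oxidation enzymes. Without Cyp4a14 the median of that list lay -0.0247 from the median of all genes, but its members went both ways, so this value does not decide. With quantile normalization the list was called up with a median 0.46 above that of all genes, so a shared rise stays open. Ppara itself fell by 1.55.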
